A study of Mus musculus with 6 samples.

How the data were processed

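Total liver RNA of 6 mice was measured on 1 oligonucleotide array per mouse, 3 TLR3-/- and 3 TLR3wt. The mice were separate animals, since the series design gives 3 mice per group, so the spread between arrays holds the spread between animals. Groups were taken from the sample titles, and the table held 0 columns of other samples.

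The deposited values are on a log2 scale and were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, normalises by quantiles and summarises the probes of a probe set, and no further scaling was applied here. The deposited table holds 35557 probe sets, and its lowest value is exactly 5 on each array. Between 57.2% and 57.6% of the values of an array stood at this floor, so each column had a median of 5. A difference with values at the floor on one side is understated, and a group with all 3 arrays at the floor gives only a bound, printed as "at least N-fold" from the other group's mean against 5. List medians count such a gene at that bound. What set the floor is not given in the sources used here.

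Gene names came from the array annotation supplied with the table, updated through gene identifiers to the reference table of assembly GRCm38.p6, which held 99.6% of them. Of all probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had none. No gene was named from a probe set with several symbols. The genome build behind the array annotation is not given in the sources used here, so the reference table served only for names and for the order of genes along a chromosome.

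Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with default settings, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with the group as the only term. The plan, fixed before the data were examined together with the tests, the gene lists, the naming rule and most alternatives, set no filter on signal for the reported fit, and a filter on low values only as an alternative. The reported fit departs from it: the 18918 probe sets at the floor on all 6 arrays were left out, and 16639 were tested. This departure was made after the values had been seen. Several filters on the floor and the planned fit were first run side by side, so the choice was not blind to their counts. The reason for it was that probe sets with no spread at all enter limma's estimate of the common variance. The prior degrees of freedom were 2.20 without them and 0.0626 with them. The planned fit over all 35557 probe sets called 0, and that count stands beside the reported one in the text.

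Gene lists for pathways and cell types were fixed in advance, 42 lists with 984 names, of which 3 names matched no gene. For these, each gene was represented by the probe set with the highest mean over all 6 arrays, which gave 10347 genes. The 36 lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, which compares a list with the other genes, and adjusted over the lists. Camera with a correlation estimated from the residuals and fry were run as alternatives. The fry p tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Called genes among the 100 tested genes on each side of Tlr3 were compared with the other genes by Fisher's exact test, two-sided.

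The text names Tlr3, up to 12 called genes per direction with 1 symbol and non-overlapping groups, where fewer passed the 5 genes of each direction with the smallest unadjusted p among those that did not pass, up to 4 passing members of each list or else the 3 with the smallest unadjusted p, and up to 6 called neighbours of Tlr3. List members that passed adjusted over the list alone are named as well where few did. Outside these rules, the sex-chromosome genes come from a fixed list with too few measured members for a test, and the members of the BMP-SMAD and glucocorticoid lists were named after their values were seen. Other genes named outside the rules are marked in the text.

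The procedure was tested on simulated data with 200 changed probe sets among 16633 for the comparison of TLR3-/- with TLR3wt. It recovered 46.4% of changes of 0.5 on the log2 scale, 84.9% of changes of 1 and 98.6% of changes of 2. There were 7 false calls among 165. Changes were placed only in probe sets with a mean more than 1 above the floor, and noise was independent between probe sets. The recovery rates do not cover probe sets near the floor, and the false calls do not cover correlated or identical ones. In a simulation of lists over 10343 genes, with noise drawn independently for each gene, the shifted list was called (camera adjusted p = 5.21e-10). Of 35 other lists, 0 were called. Genes of the real lists were correlated (estimated correlation 0.65 for macrophage markers and 0.81 for acute-phase genes). False calls that such correlation brings could not appear in this simulation.

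Alternatives covered quantile normalisation again, the variance model, array weights, the test, the replicate number as a block, leaving out each mouse, the probe sets entering the fit, thresholds, the window around Tlr3 and the list test. The number of arrays limits the precision.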

Results

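Liver transcripts of untreated mice at 3 months of age were compared between 3 TLR3-/- mice and 3 TLR3wt mice, all of the C57Bl/6 strain. TLR3 is an endosomal receptor for double-stranded RNA that signals through the adaptor TRIF. The comparison asks which liver transcripts differ with the TLR3 genotype in the absence of a treatment. Each array had between 15081 and 15226 probe sets above the floor of 5 (log2 RMA signal), and over the tested probe sets the array medians lay between 6.54 and 6.59. Over these probe sets, correlations between arrays were 0.984 to 0.991 within groups and 0.980 to 0.988 between groups. The first principal component (39.5% of the variance) separated the groups, and the second (22.2%) set TLR3wt replicate 3 (-17.6) apart from TLR3wt replicates 1 and 2 (14.5 and 11.1). The Y-linked genes Eif2s3y, Kdm5d and Uty were above the floor in all 6 livers and Xist was at the floor in all 6.

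The targeted gene itself could not be compared. The Tlr3 probe set (10578493) stood at 5 on all 3 TLR3-/- arrays and on all 3 TLR3wt arrays. The array thus gave no Tlr3 difference, no fold and no check of the genotype labels.

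The largest called differences in named genes were opposite changes of Hamp and Igfbp1. Hamp (probe set 10562169), which encodes the iron-regulatory hormone hepcidin, was 10.41 ± 0.15 in TLR3-/- and 7.84 ± 0.58 in TLR3wt livers (log2 signal, mean ± SD, n = 3 each), a 5.95-fold rise (limma adjusted p = 0.0465). Igfbp1 (10374223), a secreted binding protein of insulin-like growth factors, was 7.57 ± 0.57 against 10.12 ± 0.07, a fall of 5.84-fold (limma adjusted p = 0.0465). Mid1 (10603208), a microtubule-associated ubiquitin ligase, rose from 5.72 ± 0.33 to 7.32 ± 0.11, and Ppp1r3b (10571321), a glycogen-targeting subunit of protein phosphatase 1, fell from 8.32 ± 0.10 to 7.09 ± 0.13 (limma adjusted p = 0.0465 and 0.0406). The zinc transporter gene Slc39a4 (10430006) fell from 8.86 ± 0.12 to 7.85 ± 0.16. These calls were made without the probe sets at the floor on all arrays, and in the planned fit, which held them, none of the called genes passed (limma adjusted p 0.370 to 0.410).

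The other called genes moved less. Rmdn2 (10447079) was higher in TLR3-/- livers by 0.55 on the log2 scale. The log2 differences, TLR3-/- minus TLR3wt, were -0.90 for Nabp1 (10354418), -0.90 for Tceal8 (10606858), -0.78 for Sirpa (10476021), which encodes an inhibitory receptor of myeloid cells, -0.69 for Mpp7 (10457357) and -0.62 for Fam25c (10418917). In each of the 11 called genes with 1 symbol, the 3 livers of one group all lay above the 3 of the other. After quantile normalisation again, only Ppp1r3b and Tceal8 of these genes passed (limma adjusted p = 0.0476 for both). With an ordinary pooled-variance test none of them passed (adjusted p 0.191 to 0.210). In the 6 fits without 1 mouse, Hamp and Igfbp1 each passed in 1 and the others in none. With 1-symbol probe sets alone, 1 passed, a lower one, so Hamp, Mid1 and Rmdn2 did not. With identical probe sets entered once, 3 of the 31 called probe sets passed, 2 higher and 1 lower. In either fit at most 1 of the lower genes passed.

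In all, 31 of 16639 tested probe sets passed limma's adjusted p of 0.05, 23 higher and 8 lower in TLR3-/- livers, and the planned fit that also held the probe sets at the floor on all arrays passed 0 of 35557 (2018 at an unadjusted p under 0.05). Of the 31, 11 had 1 symbol (3 higher, 8 lower), 1 had several and 19 had none. Those 19 were all higher but held 9 distinct profiles, since sets of 7, 4 and 2 probe sets carried identical values. The called probe sets lay close to the threshold (limma adjusted p 0.0406 to 0.0465), and 2406 had an unadjusted p under 0.05 (1533 higher, 873 lower) where chance gives 832. The groups did not overlap in 3337 tested probe sets (20.1%, where chance gives 10%). Leaving out TLR3wt replicate 1, 2 or 3 gave 0, 0 and 13 calls in limma, and leaving out TLR3-/- replicate 1, 2 or 3 gave 1, 1 and 0. The 3 fits with 0 calls had 2577, 1771 and 2203 probe sets at an unadjusted p under 0.05. Entering probe sets with identical values once gave 3, centring the arrays gave 14 (8 higher, 6 lower), and testing probe sets with 1 symbol alone gave 1.

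Some genes close behind did not pass. Id3, an inhibitor of helix-loop-helix factors, was 7.48 ± 0.30 in TLR3-/- and 6.06 ± 0.19 in TLR3wt livers (limma adjusted p = 0.0617), and the sulfotransferase gene Sult5a1 was 6.70 ± 0.38 and 5.14 ± 0.12 (limma adjusted p = 0.0633). Gm10319 and Ppp1r9a had log2 differences of 0.77 and 0.57, and Gm9909, at the floor on all TLR3wt arrays, was at least 1.49-fold higher. On the lower side, Stk17b, Slfn2, Pld4 and Eif4e3 had log2 differences of -0.86, -0.56, -0.81 and -0.41, and Cd300ld, at the floor on all TLR3-/- arrays, was at least 1.46-fold lower. The smallest adjusted p among these lower genes was 0.0546 (limma, Eif4e3).

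**Figure D1:**
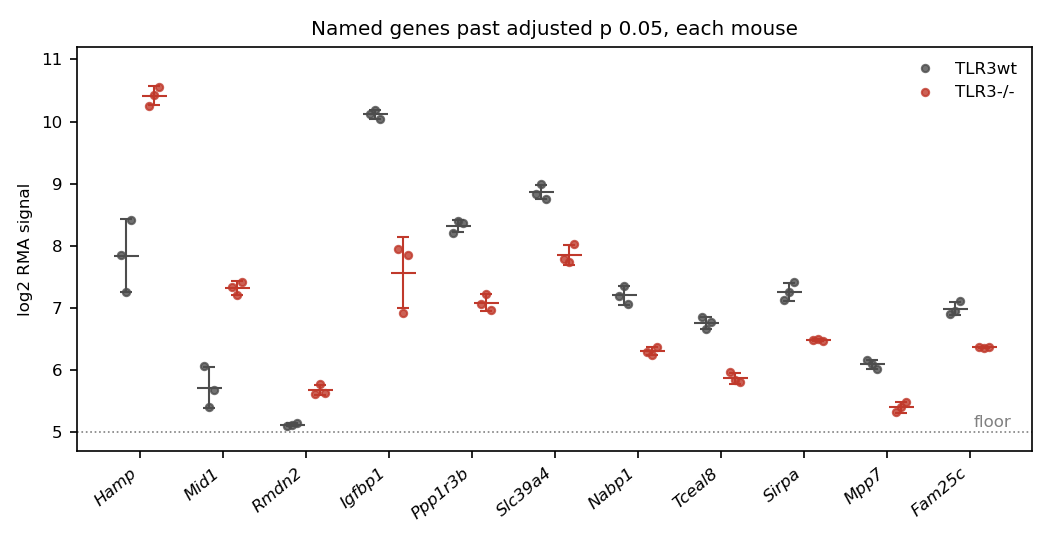
Log2 RMA signal (vertical axis) of the 11 called genes with 1 symbol in each liver, with mice as points (3 per group), group means as horizontal ticks, SD as bars and the floor at 5 as a dotted line. Hamp lay between 10.3 and 10.6 in the TLR3-/- livers and between 7.25 and 8.42 in the TLR3wt livers.

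The chromosome around Tlr3 held 1 called gene among those with 1 symbol and a position. This window was tested because a targeted allele made in cells of another strain carries flanking chromosome with it. Effects of such flanking sequence and of the loss of TLR3 cannot be told apart in this design. With 1 called gene, the test cannot exclude flanking effects. The 19 called probe sets without a symbol and the 1 with several symbols were not placed, so any of them near Tlr3 went uncounted. Ppp1r3b had 19 tested genes between it and Tlr3 and was the 1 called gene among the 200 nearest, against 8 among 10127 other genes with a position (Fisher's exact test, two-sided, p = 0.161, adjusted over 2 tests 0.323). At an unadjusted p under 0.05 the shares were 18.0% (36 genes) and 15.6% (1582 genes; Fisher's exact p = 0.376). The call of Ppp1r3b was lost without any 1 of the 6 mice, TLR3wt replicates 1, 2 and 3 and TLR3-/- replicates 1, 2 and 3 alike, which left 0 called neighbours, and in the planned fit, which also gave 0.

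Macrophage markers and immune genes lay lower in the TLR3-/- livers. Of 20 markers of macrophages and Kupffer cells, the resident macrophages of the liver, 19 were lower, with a median log2 difference of -0.76. Adgre1, an adhesion receptor gene of macrophages, was 6.04 ± 0.28 against 7.04 ± 0.22, the Kupffer cell receptor gene Timd4 was 5.43 ± 0.16 against 6.33 ± 0.23, and the scavenger receptor gene Marco was 5.69 ± 0.23 against 6.77 ± 0.37 (SD, n = 3 each). Adjusted over the list alone 16 markers passed, all lower, and over all probe sets 0 passed. The list passed camera (adjusted p = 7.41e-15), with adjusted p = 0.281 with an estimated correlation. The mean of the markers was -0.54, -0.95 and -0.47 in TLR3-/- replicates 1 to 3, against -0.22, 0.20 and 0.02 in TLR3wt replicates 1 to 3 (log2, relative to the TLR3wt mean).

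Interferon-response genes were lower too. The RNA came from whole liver, so changes within cells and changes in the share of cells were not told apart for these and the following immune lists. Of 15 interferon-gamma-response genes 13 were lower (median -0.32, or -0.17 in the brighter part of the tested probe sets), and 7 passed adjusted over the list alone against 0 over all probe sets. Among them, Cxcl9, a T-cell chemokine gene, was 5.49 ± 0.42 in TLR3-/- and 7.05 ± 0.33 in TLR3wt livers, and the guanylate-binding protein genes Gbp8 and Gbp9 had differences of -0.53 and -0.47. Camera gave adjusted p = 1.89e-08, and adjusted p = 0.281 with an estimated correlation. Of 27 type I interferon-stimulated genes 22 were lower (median -0.15, or -0.05 in the brighter part), 6 adjusted over the list alone and 0 over all probe sets. Herc6, Trim30a and Cmpk2 had differences of -0.53, -0.45 and -0.48. This list passed camera (adjusted p = 8.62e-08), had adjusted p = 0.104 with an estimated correlation, the smallest of the 36 lists, and was the 1 list that passed fry (adjusted p = 0.00842).

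Antigen presentation and inflammatory signalling genes followed the same direction. Of 13 MHC class I genes 12 were lower (median -0.15), and the immunoproteasome genes Psmb8 (-0.46) and Psmb10 (-0.45) passed adjusted over the list alone, with 0 over all probe sets, while H2-Q2 had a difference of -0.22 (camera adjusted p = 1.73e-05, adjusted p = 0.281 with an estimated correlation). All 5 measured MHC class II genes were lower (median -0.46, or -0.04 in the planned fit), among them H2-Ab1 (-0.50), H2-Eb1 (-0.46) and Cd74 (-0.43), with 0 adjusted over the list alone or over all probe sets. The camera result was adjusted p = 0.0163 for them, adjusted p = 0.452 with an estimated correlation, and 0.0604 without TLR3-/- replicate 1. TLR3wt replicate 2 carried much of this difference. The mean of these genes was 0.49 in that mouse and -0.33 and -0.16 in TLR3wt replicates 1 and 3, against -0.54, -0.35 and -0.26 in the TLR3-/- livers, so the groups overlapped. Without TLR3wt replicate 2 only 4 of the genes were measured, too few for a test (median -0.16), with H2-Ab1 at -0.23, H2-Eb1 at -0.15 and Cd74 at -0.17, and without TLR3wt replicate 1 Cd74 was at -0.67. Of 19 NF-kappaB target genes 14 were lower (median -0.16, or -0.09 without TLR3wt replicate 1), 5 adjusted over the list alone and 0 over all probe sets. In the planned fit, where members at the floor enter as 0, the median was -0.01. The cytokine gene Il1b and the NF-kappaB inhibitor gene Tnfaip3 were at the floor on all TLR3-/- arrays, at least 1.80-fold and 1.23-fold lower, and the adhesion molecule gene Vcam1 was lower by a log2 difference of -0.93 (camera adjusted p = 0.000248, adjusted p = 0.281 with an estimated correlation).

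Nucleic acid receptors showed small differences. Of 10 cytosolic nucleic acid sensors 9 were lower (median -0.07), including Zbp1 (-0.49), Ifih1 (-0.15) and Ifi203 (-0.25, or -0.14 without TLR3wt replicate 3), with 0 adjusted over the list alone or over all probe sets. By camera the list had adjusted p = 0.0176 and adjusted p = 0.281 with an estimated correlation, with 0.0797 without TLR3-/- replicate 3, 0.114 with probe sets above the floor on all arrays and a median of -0.11 without TLR3wt replicate 1. Of 15 Toll-like receptors and adaptors other than Tlr3, 9 were lower (median -0.07), and Tlr2 (-0.39) passed adjusted over the list alone, with 0 over all probe sets, while Irf7 and Irak2 had differences of -0.38 and 0.12. Its camera adjusted p was 0.0446, with adjusted p = 0.281 with an estimated correlation, and 0.121, 0.0642, 0.0716 and 0.0627 without TLR3wt replicate 2, TLR3wt replicate 3, TLR3-/- replicate 1 and TLR3-/- replicate 2. The list also lost its call with camera on ranks (0.0795), with the brighter part of the tested probe sets (0.0786) and in the planned fit (0.0947).

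**Figure D2:**
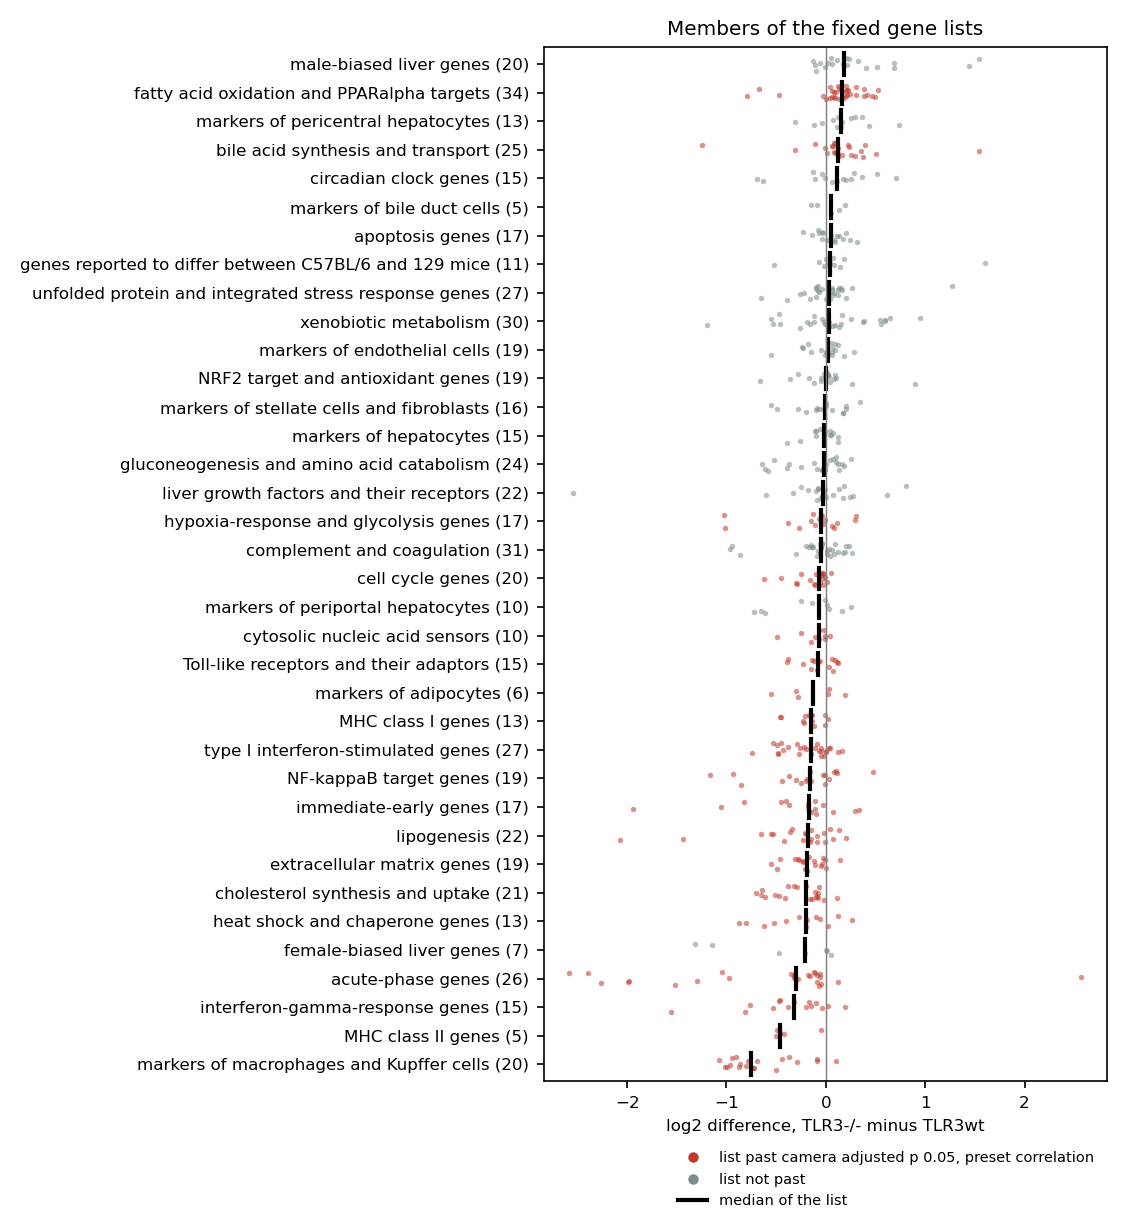
Log2 difference, TLR3-/- minus TLR3wt (horizontal axis), of each measured member of the 36 tested lists (vertical axis, number of members in brackets), with genes as points, list medians as black bars and red for the 19 lists past camera's adjusted p of 0.05 at its preset correlation. The macrophage list had the lowest median, -0.76.

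Most acute-phase genes were lower, with Hamp and Saa4 higher. Of 26 measured genes 24 were lower (median -0.30), Saa4 had a difference of 0.12, named after its value was seen, and Hamp, itself counted in this list, was the 1 member that passed, higher, both adjusted over the list alone and over all probe sets. Camera gave adjusted p = 6.74e-06, and adjusted p = 0.488 with an estimated correlation. The mean of these genes was 0.77 in TLR3wt replicate 3 and -0.49 and -0.28 in TLR3wt replicates 1 and 2, against -0.75, -0.56 and -0.52 in TLR3-/- livers, and the median was -0.08 without TLR3wt replicate 3. Of 17 immediate-early genes 14 were lower (median -0.17, or -0.61 in the brighter part of the tested probe sets and -0.10 in the planned fit). The phosphatase gene Dusp1 was lower by a log2 difference of -1.05 and passed adjusted over the list alone, with 0 over all probe sets, and Gadd45g and Jund had differences of -1.94 and -0.18 (camera adjusted p = 0.000213, adjusted p = 0.281 with an estimated correlation).

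Most lipid synthesis genes had lower and most fatty acid oxidation genes higher group means in TLR3-/- livers, while the per-mouse means of these 3 lists overlapped between the groups. Of 21 genes of cholesterol synthesis and uptake 20 were lower (median -0.20), among them Sqle (-0.66), Cyp51 (-0.32) and Dhcr7 (-0.51), enzymes of sterol synthesis, with 0 adjusted over the list alone or over all probe sets. The camera result was adjusted p = 4.99e-07, adjusted p = 0.391 with an estimated correlation, and a median of -0.12 without TLR3-/- replicate 3. Of 22 lipogenesis genes 18 were lower (median -0.18), with 0 adjusted over the list alone or over all probe sets, among them the phosphatidate phosphatase gene Lpin1 (-2.07), the desaturase gene Fads2 (-0.34) and Pgd (-0.42). That list had camera adjusted p = 0.000608 and adjusted p = 0.488 with an estimated correlation, and its median was -0.11 without TLR3wt replicate 1, -0.38 without TLR3-/- replicate 1 and -0.04 without TLR3-/- replicate 3. The mean of the lipogenesis genes was 0.08 in TLR3-/- replicate 1, within the TLR3wt range of -0.13 to 0.10, and -0.51 and -0.55 in TLR3-/- replicates 2 and 3. Of 34 genes of fatty acid oxidation and PPARalpha targets 30 were higher (median 0.16), with 0 adjusted over the list alone or over all probe sets. The dehydrogenase gene Acadl (0.24) and Ech1 (0.20) were among the higher ones and the hormone gene Fgf21 (-0.67) among the lower. By camera the list had adjusted p = 0.0283, adjusted p = 0.652 with an estimated correlation, and 0.213 and 0.384 without TLR3wt replicate 3 and TLR3-/- replicate 2, where the median was 0.09 and 0.08, and 0.0525 with the brighter part of the tested probe sets. The mean of these genes was 0.34 in TLR3-/- replicate 2 and 0.04 and -0.00 in TLR3-/- replicates 1 and 3, against -0.10 to 0.09 in TLR3wt livers.

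Bile acid genes were mostly higher, with Cyp7a1 the other way. Of 25 genes of bile acid synthesis and transport 21 were higher (median 0.12). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 7.93 ± 0.34 in TLR3-/- and 9.18 ± 0.46 in TLR3wt livers, and it and the exporter gene Abcc4 (-0.31) passed as lower and Hsd3b7 (0.35) as higher adjusted over the list alone, with 0 over all probe sets. Camera gave adjusted p = 0.0431, adjusted p = 0.415 with an estimated correlation, and 0.0964, 0.161 and 0.0785 without TLR3wt replicate 3, TLR3-/- replicate 1 and TLR3-/- replicate 3. The call was also lost with array weights (0.0642) and with probe sets above the floor on all arrays (0.0541).

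The remaining lists that passed camera held matrix, cell cycle, heat shock, hypoxia and glycolysis genes and adipocyte markers. Of 19 extracellular matrix genes 18 were lower (median -0.19), and Sparc (-0.47) and Col4a1 (-0.31) passed adjusted over the list alone, with 0 over all probe sets, beside Col4a2 (-0.27). The camera result was adjusted p = 7.93e-06 and adjusted p = 0.391 with an estimated correlation, and the median was -0.09 without TLR3wt replicate 3 and -0.11 without TLR3-/- replicate 3. Of 20 cell cycle genes 18 were lower (median -0.06, or -0.10 without TLR3wt replicate 1), with 0 adjusted over the list alone or over all probe sets. The replication licensing genes Mcm5 and Mcm2 had differences of -0.29 and -0.25 (Mcm2 -0.16 without TLR3wt replicate 3), and Mcm6, at the floor on all TLR3-/- arrays, was at least 1.54-fold lower (camera adjusted p = 0.000453, adjusted p = 0.391 with an estimated correlation). Of 13 heat shock and chaperone genes 10 were lower (median -0.20), among them Dnajb1 (-0.88), Hspa1a (-0.52) and Bag3 (-0.62), the last at -0.37 and Hspa1a at -0.33 without TLR3wt replicate 2, with 0 adjusted over the list alone or over all probe sets. By camera the list had adjusted p = 0.0033, adjusted p = 0.452 with an estimated correlation, and 0.110 without TLR3-/- replicate 1, and the median was -0.11, -0.30, -0.06, -0.39 and -0.12 without TLR3wt replicate 2, TLR3wt replicate 3, TLR3-/- replicate 1, TLR3-/- replicate 2 and TLR3-/- replicate 3.

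Of 17 genes of hypoxia response and glycolysis 12 were lower (median -0.05), with 0 adjusted over the list alone or over all probe sets, among them P4ha1 (-1.02) and Aldoa (-0.27), with Slc2a1 (0.30) higher. Camera gave adjusted p = 0.0266, adjusted p = 0.281 with an estimated correlation, and 0.0733 and 0.115 without TLR3wt replicate 3 and TLR3-/- replicate 3, with medians of -0.02 without TLR3wt replicate 3 and -0.08 without TLR3wt replicate 2. Of 6 measured adipocyte markers 3 were lower and 3 higher (median -0.13), with Plin4 (-0.55) and Cd36 (-0.28) past adjusted over the list alone and 0 over all probe sets, and Fabp4, at the floor on all TLR3-/- arrays, at least 1.23-fold lower (1.10-fold without TLR3wt replicate 3). The camera result was adjusted p = 0.0431 for these markers and adjusted p = 0.281 with an estimated correlation. It gave 0.0828, 0.0630, 0.0632 and 0.0797 without TLR3wt replicate 1, TLR3wt replicate 2, TLR3-/- replicate 2 and TLR3-/- replicate 3, with medians of -0.21 without TLR3-/- replicate 1 and -0.09 without TLR3-/- replicate 3. The list also lost its call after quantile normalisation again (0.0608), with the replicate block (0.0607), with camera on ranks (0.141) and in the planned fit (0.0925).

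Together 19 of the 36 lists passed camera at its preset correlation, 17 lower and 2 higher, 0 passed with an estimated correlation and 1 passed fry. Over all probe sets, 3 list members passed (Hamp, Igfbp1 and Mid1). In the planned fit 17 lists passed. Splits of the 6 mice that mixed the groups passed 5 to 13 lists by camera at its preset correlation. The per-mouse means separated the groups in 12 of the 19 lists, and overlapped for cholesterol, extracellular matrix, lipogenesis, heat shock, MHC class II, fatty acid oxidation and bile acid genes. They also separated the groups in lists that did not pass, among them hepatocyte, periportal and pericentral markers. Separation alone thus does not set the called lists apart.

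Markers of the other cell types of the liver did not pass. Endothelial markers had a median of 0.02 and a mean of -0.02 over 19 genes, while camera's direction was down (adjusted p = 0.319), with Pecam1, Lyve1 and Vwf at -0.24, -0.56 and -0.18 (Lyve1 -0.36 without TLR3-/- replicate 3). Stellate cell and fibroblast markers had a median of -0.01 over 16 genes (camera adjusted p = 0.563), with Pdgfra (0.34), Ecm1 (0.20) and Col3a1 (-0.55, or -0.34 without TLR3wt replicate 3). Hepatocyte markers had a median of -0.01 over 15 genes (camera adjusted p = 0.174), with Tat (-0.39), Hnf4a (-0.26) and Apoc3 (0.12). Bile duct markers had a median of 0.05 over 5 genes, opposite to camera's direction (adjusted p = 0.605), with Krt8 (-0.15), Krt18 (0.13) and Pkhd1 (-0.09). Krt18 was at 0.06, 0.20 and 0.07 without TLR3wt replicate 2, TLR3wt replicate 3 and TLR3-/- replicate 2, and Pkhd1 at -0.14 and -0.04 without TLR3-/- replicate 2 and TLR3-/- replicate 3. Periportal markers had a median of -0.07 over 10 genes (camera adjusted p = 0.0939), with Pigr (0.25), Ctsc (-0.73) and Pck1 (-0.61), and pericentral markers 0.15 over 13 genes (camera adjusted p = 0.207), with Tbx3 (0.74), Cyp2e1 (0.25) and Lect2 (0.43), the latter pair at 0.14 and 0.24 without TLR3wt replicate 3. Adjusted over the list alone, Pigr passed and 0 of the other markers of these lists did, and over all probe sets 0 passed. Lists with fewer than 5 measured members were not tested. They were T and NK cell markers (3 measured), B and plasma cell markers (1), neutrophil markers (2), red cell markers (3), pancreatic acinar markers (2) and sex-chromosome genes (3).

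**Figure D3:**
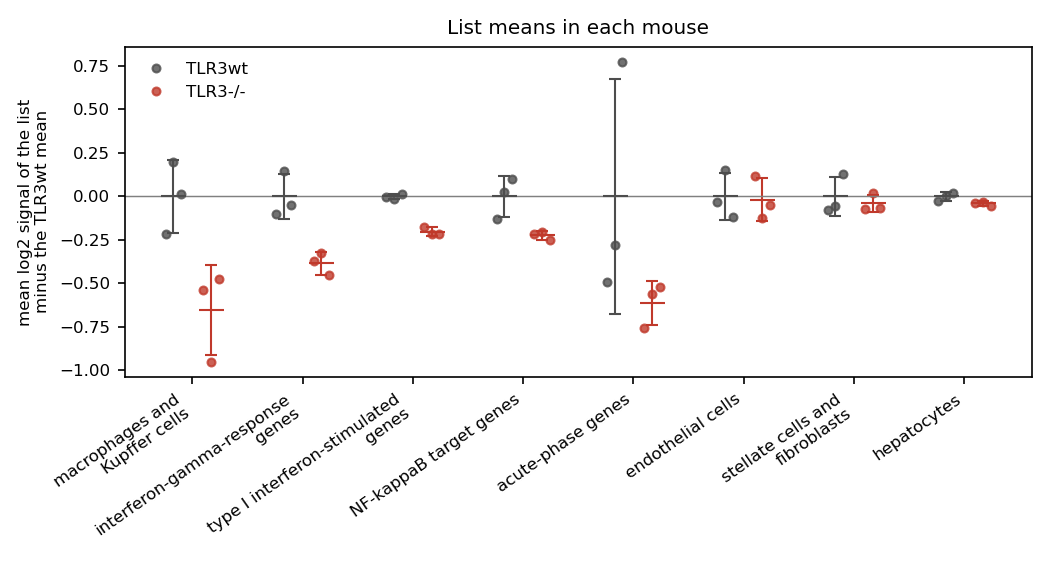
Mean log2 signal of the members of 8 lists in each liver, relative to the TLR3wt mean (vertical axis), with mice as points (3 per group), group means as horizontal ticks and SD as bars. The macrophage, interferon, NF-kappaB, acute-phase and hepatocyte lists separated the groups, and the endothelial and stellate lists did not. TLR3wt replicate 3 stood at 0.77 for acute-phase genes.

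Other metabolic and stress lists did not pass either. Among 31 complement and coagulation genes (median -0.05, camera adjusted p = 0.106), C1qb (-0.96) and C1qc (-0.94), which are also in the macrophage list, passed adjusted over the list alone, with 0 over all probe sets, and C8g had a difference of 0.26. Among 22 liver growth factors and receptors (median -0.03, camera adjusted p = 0.174), Igfbp1 passed over all probe sets, and adjusted over the list alone Igfbp1, Il6ra and Tgfb1 passed as lower and Igfbp2 as higher. The 24 genes of gluconeogenesis and amino acid catabolism had a median of -0.01 (camera adjusted p = 0.0687), with Slc38a2 at -0.58. The 19 NRF2 target and antioxidant genes had a median near 0 (camera adjusted p = 0.218), with Hmox1, Ugdh and Osgin1 at -0.66, -0.28 and 0.90 (Osgin1 0.55 without TLR3wt replicate 2). The 27 genes of the unfolded protein and integrated stress response had a median of 0.04, opposite to camera's direction (adjusted p = 0.319), with Herpud1, Trib3 and Ddit3 at -0.65, 0.27 and -0.39 (Ddit3 -0.25 without TLR3-/- replicate 1). The 17 apoptosis genes had a median of 0.05 (camera adjusted p = 0.818), with Casp9, Xiap and Bbc3 at 0.24, 0.20 and 0.12. In these last 4 lists 0 genes passed adjusted over the list alone or over all probe sets.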

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

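Apart from the planned fit itself, the alternatives on the floor, on centring over the tested probe sets, on the brighter part of the tested probe sets, on identical probe sets and on members shared with macrophage markers were chosen after seeing the data. The count of 31 called probe sets was 0 in the planned fit with the floor included, 42 and 42 with probe sets above the floor on at least 2 or 5 arrays, 18 with those above it on all arrays, 9 after quantile normalisation again (9 of the 31), 14 after median centring (14 of the 31), 2 with an ordinary pooled-variance test (0 of the 31), 1 with 1-symbol probe sets alone, 3 with identical probe sets entered once and 95 at adjusted p 0.1. Without 1 mouse it ranged from 0 to 13. Fewer mice explain part of that drop by construction, and otherwise the cause was not tested. It stayed within 1.5 times of 31 under the trend (36), robust (30), array weight (35), 1.5-fold (28) and brighter-part (21) settings. Only 12 of the 21 brighter-part calls were among the 31.

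Called neighbours of Tlr3 numbered 1, but 0 with the replicate block, 0 in the planned fit, 0 to 0 without 1 mouse and 2 at adjusted p 0.1. The number of lists past the threshold was 19, but 0 with an estimated correlation and 1 by fry, and 14 to 22 under the other alternatives (16 to 20 without 1 mouse). Of the 19 lists, 11 passed in all 6 fits without 1 mouse. None of the 118 genes named by the rule changed sign under the alternatives run for it, and the other genes in the text were not run one by one. The trend, robust, pooled-variance, block and planned fits leave a gene's difference as it is, so they could not turn a sign. In the same way, a change of the list test alone cannot move a list's median. Alternatives were run for the 19 lists that passed, not for the other 17, and no median among the 19 changed sign, but several moved by more than 1.5 times. In the planned fit, where list members at the floor enter as 0 by construction, the medians of Toll-like receptor, cell cycle and adipocyte genes were 0, and those of NF-kappaB targets, MHC class II genes, nucleic acid sensors, type I interferon-stimulated, interferon-gamma-response, acute-phase, immediate-early and extracellular matrix genes were -0.01, -0.04, -0.01, -0.08, -0.17, -0.17, -0.10 and -0.11. In the brighter part of the tested probe sets the medians of type I interferon-stimulated, interferon-gamma-response and immediate-early genes were -0.05, -0.17 and -0.61. With probe sets above the floor on all arrays that of the nucleic acid sensors was -0.02, and after quantile normalisation again that of hypoxia and glycolysis genes was -0.10.

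Replicate numbers did not pair the mice: same-numbered arrays correlated at 0.05, -0.01 and -0.06 in their deviations from the group means, and 1 of 6 arrays matched its own number best. With the replicate block 4 probe sets passed, all among the 31, and 18 lists, without the adipocyte markers (adjusted p 0.0607). The planned centring of whole columns and the filter at the median of all means, planned only for comparison with the unfiltered fit, were not run, since each column median and the median of all means equal the floor. No alternative gave a Tlr3 value, since it was at the floor on all arrays. Signal over background is a limit here, beside the number of mice, since differences of genes near 5 are understated.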

Other observations

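The tests on non-parenchymal markers, BMP-SMAD targets, acute-phase genes, Hamp2, glucocorticoid-induced genes and lipogenesis genes were chosen after the patterns had been seen, and for the non-parenchymal, acute-phase and lipogenesis genes after the tested values had been seen as well, as was the bound of 2 standard errors over mice.

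Genes that distinguish mouse strains, sexes and times of day were also measured. Mid1 was fixed beforehand among genes reported to differ between C57BL/6 mice and mice of the strain from which many embryonic stem cell lines came. In that list of 11 measured genes (median 0.04, camera adjusted p = 0.706), Mid1 passed over all probe sets. Adjusted over the list alone, Mid1 passed as higher and Wdfy1 (-0.52) as lower, while Nnt had a difference of 0.09. Camera looks for a shared direction, which strain differences need not have, so it cannot exclude them. The mixed p of fry, which counts differences in either direction, was 3.62e-05 for this list, unadjusted. It was 1.99e-05 for apoptosis genes, so it did not single out the strain list. Male-biased liver genes had a median of 0.19 over 20 genes (camera adjusted p = 0.222), with Susd4, Cyp2u1 and Cyp7b1 at 1.44, 0.68 and 1.54, and female-biased genes a median of -0.21 over 7 (camera adjusted p = 0.0781), with Cyp17a1 and Abcd2 at -1.31 and -1.15 and Cyp2b9 at the floor on all TLR3-/- arrays and on 2 of 3 TLR3wt arrays. TLR3wt replicate 3 stood apart in both lists, with a mean of 0.42 for female-biased genes against -0.22 and -0.20 in TLR3wt replicates 1 and 2, and of -0.34 for male-biased genes against 0.18 and 0.15. Without it Cyp7b1, Cyp17a1 and Abcd2 were at 0.82, -0.60 and -0.57. Circadian clock genes had a median of 0.11 over 15 (camera adjusted p = 0.818), with Hlf and Cry2 at 0.36 and 0.51 and Per1, at the floor on all TLR3-/- arrays, at least 1.55-fold lower. Clock genes need not share a direction either (9 higher, 6 lower), so camera cannot exclude a difference in the hour of sampling. Among 30 genes of xenobiotic metabolism (median 0.03, camera adjusted p = 0.922), Cyp3a25 (0.39) and Nr1i3 (0.59), which encodes the nuclear receptor CAR, passed as higher adjusted over the list alone, beside Cyp2c54 (0.65). Over all probe sets 0 genes of the sex-biased, clock and xenobiotic lists passed. Nnt and Wdfy1 were named after their values were seen.

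Macrophage markers were lower in the TLR3-/- livers (median -0.76). A smaller share of all non-parenchymal cells alike would lower endothelial and stellate markers about as much. Yet the median of those 35 markers lay above that of the macrophage markers by 0.762 (95% bootstrap interval over genes 0.476 to 0.924). Per mouse, the macrophage mean less the mean of those markers differed between TLR3-/- and TLR3wt livers by -0.62 ± 0.17 (SE). The interval takes genes as independent, while the estimated correlation of the macrophage markers was 0.65. A lesser fall of the other non-parenchymal cells stays open. Of 19 extracellular matrix genes 18 were lower (median -0.19), against 7 of 19 endothelial and 9 of 16 stellate markers. A single mouse did not set the macrophage difference, since the leave-one-out medians ran from -0.913 to -0.535. Fewer Kupffer cells, or Kupffer cells with less of these transcripts, may account for it and were not told apart by any test here.

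Hamp was higher in the TLR3-/- livers while 24 of 25 other acute-phase genes were lower (median -0.314, 95% bootstrap interval over genes -1.05 to -0.105), opposite to what inflammatory induction would give, but this explanation stays open since the per-mouse means differed by -0.74 ± 0.40 (SE), within 2 standard errors, and the median was -0.12 without TLR3wt replicate 3. A list of 8 BMP-SMAD target genes, chosen after Hamp and Id3 had been seen, had a median of 0.247, with 8 of 8 higher (limma camera p = 0.000605, p = 0.0469 with an estimated correlation, fry p = 0.00774), among them Id2 (0.97), Atoh8 (0.57) and Smad7 (0.52). None of the 8 passed over all probe sets (limma adjusted p 0.194 to 0.687). Id1 (0.18), Id4 (0.26) and Smad6 (0.14) had signals near the floor, with 2 arrays of Id4 at it. Stronger BMP-SMAD signalling in these livers is a candidate explanation only. Signal from the near-identical gene Hamp2 stays open: its own probe set differed by 0.215, under the bound set in advance, but 3 of its 6 arrays were at the floor, so that difference is understated and the bound cannot be used.

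Igfbp1, Lpin1, Mt1, Gadd45g and Dusp1, which glucocorticoids can induce, were lower together (differences of -2.55, -2.07, -1.98, -1.94 and -1.05), a group picked after the values were seen, of which Igfbp1 passed over all probe sets and the other 4 did not (limma adjusted p = 0.214, 0.326, 0.183 and 0.0994). In a list of 12 other glucocorticoid-induced genes, 10 of 10 measured were lower, with a median of -0.679 (limma camera p = 7.46e-08, p = 0.00493 with an estimated correlation, fry p = 0.00116), among them Zbtb16 (-1.16), Tsc22d3 (-0.78) and Fkbp5 (-0.74). One member, Mt2, is also in the acute-phase list, whose result had been seen, and without it 9 of 9 were lower (median -0.646, limma camera p = 1.93e-07, p = 0.00564 with an estimated correlation, leave-one-out medians -0.674 to -0.522). A longer fast of the TLR3wt mice would leave lipogenesis genes higher in TLR3-/- livers, and their median without Lpin1 was -0.156 (95% bootstrap interval over genes -0.338 to -0.0853), but a fast stays open since it was -0.04 without TLR3-/- replicate 3 and the per-mouse means differed by -0.24 ± 0.20 (SE). A difference in glucocorticoid exposure, by handling, hour of sampling or genotype, may account for the pattern, and which of these applies was not tested.

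With 10 ways to split 6 mice into 3 and 3, no share under 0.05 can be reached. For the called probe sets, 1 of the 10 splits, the real one, gave 31 or more and the highest other gave 0. For the called neighbours of Tlr3, 1 of 10 gave 1 or more and the highest other gave 0. For the lists, 1 of 10 gave 19 or more, and the other splits gave 5 to 13. Camera at its preset correlation thus called lists in splits that mixed the groups as well.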
